A study of Mus musculus with 12 samples.

How the data were processed

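RNA-seq was made from mouse bone marrow-derived macrophages of 2 genotypes, wild type (WT, given in the labels as WTfl/fl) and MGMT knockout (KO), each treated for 24 h with the vehicle DMSO or with the STING agonist DMXAA. Each of the 4 groups has 3 libraries, 12 in all, and every library was assigned to its group from its title. Per the labels, RNA was extracted with an RNeasy kit and strand-specific mRNA libraries were sequenced on a DNBSEQ instrument. The labels do not say that the 3 samples of a group come from separate mice, so every p-value measures only the spread between these samples.

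Per the labels, the authors aligned reads to mm10 with HISAT2 and counted them with featureCounts (versions not given in the sources used here). The deposited values per library are normalized counts, a signal scaled within each of 4 tables of 6 libraries: the DMSO libraries, the DMXAA libraries, the KO libraries and the WT libraries. The authors' deposited comparison tables give, for the same 4 comparisons, a log2 fold change, a p-value and an adjusted p-value, with column headers of the kind DESeq2 writes. Dividing each library's values by its smallest step gave whole reads for 100% of values (tolerance 0.01), and the reads of a library were identical in the 2 tables that hold it. The tables list 15804, 15394, 15557 and 15788 genes for DMSO, DMXAA, KO and WT, each gene with reads in at least 2 of the 6 libraries, and 16516 symbols occur in any of them. Of these symbols, 16065 (97.3%) had a single position in the GENCODE vM21 annotation of mm10, from which all coordinates are taken.

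Libraries held 79.5 to 98.1 M reads (M, mega) in listed genes. A floor of 3 reads is 0.0306 to 0.0377 reads per M reads. Where every library of a group is at 0, a fold is given as a bound against 3 reads over the group, and where a group has 1 to 3 reads the ratio is given with its 95% counting interval. These bounds and intervals cover counting error only.

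Each comparison of 2 groups was fitted within the table that holds both. The test was limma 3.58.1 (lmFit, then eBayes with an intensity trend) on log2 of the normalized count plus a pseudocount of 1, for genes with a mean normalized count of at least 10 over the 6 libraries. Genes are called at a Benjamini-Hochberg adjusted p below 0.05, two-sided, and every adjusted p for a gene is from this limma fit unless another tool is named. The interaction is the KO minus WT difference under DMXAA minus that under DMSO, fitted over all 12 libraries from the DMSO and DMXAA tables, and it equals the difference of the 2 responses to DMXAA. Errors of log2 values are standard errors (SE) of the fit, means of normalized counts are given with their standard deviation (SD), and n is 3 libraries per group throughout. Gene lists were tested with camera of limma at its preset inter-gene correlation of 0.01, adjusted over the lists with at least 3 tested members in a comparison; each list's adjusted p is from camera. Camera with an estimated correlation and fry were alternatives. Calls of list members are given over all tested genes and, beside that, adjusted over the list alone. Medians are over the tested members, and a value given beside a gene without a unit is its log2 change or difference.

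The 41 lists, the comparisons, the tests and the rule for naming genes were fixed before the data were examined. The lists cover interferon-stimulated genes, interferon-inducible GTPases, the cGAS-STING pathway, cytokines, chemokines, NF-kappaB targets, MHC class I and class II presentation, classical and alternative activation markers, co-stimulatory and checkpoint ligands, pattern recognition receptors, cell death, cell cycle, DNA repair, p53 targets, the integrated stress and unfolded protein responses, NRF2 targets, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, LXR targets and lipid handling, lysosome and autophagy, macrophage identity, osteoclast genes, heat shock, immediate early genes, ribosomal proteins, mitochondrially encoded transcripts, genes near Mgmt, genes that differ between C57BL/6 substrains, sex-linked genes, and markers of neutrophils, monocytes, dendritic cells, B cells, T and NK cells, stromal cells, erythroid cells, mast cells and basophils, and endothelial cells and megakaryocytes. The rule names Mgmt. In each comparison of 2 groups it names the 10 genes with the highest and the 10 with the lowest log2 fold change among called genes with a mean of at least 100 and no overlap between the groups' libraries, leaving out predicted-gene, Rik and identifier-only symbols. For the interaction it names the 10 called genes with the smallest p in each direction. In each list it names the 3 members with the smallest p, and further called members only where 5 or fewer were called. Lyz2, sex-linked genes and Nnt were named as checks. Genes named outside this rule, among them Lyz1, Col1a1 and list members that run against their list, were chosen after their values were seen.

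The fit was tested on simulated data with added changes of 1.25, 1.5, 2 and 4-fold. Each change was given to 46 to 50 of the tested genes. In the real responses to DMXAA 62.8% (WT) and 66.6% (KO) of genes were called, so recovery and false calls may differ there. At 2-fold, 89.6% of the changed genes were recovered for DMXAA in WT, 88% for DMXAA in KO, 95.9% for genotype under DMSO, 80% for genotype under DMXAA and 81.6% for the interaction. At 1.5-fold recovery was 70%, 79.6%, 72%, 79.6% and 38% in the same order. At 1.25-fold it was 28.6%, 44%, 34.7%, 62% and 18%, so a gene not called may still differ by such amounts. Genes left unchanged were called 11, 16, 10, 7 and 2 times in the same order, among more than 12000 tested in each.

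Alternatives were pseudocounts of 0.5 and 5, no filter and a filter at a mean of 50, rescaling every library to the same total or the same upper quartile, robust eBayes, array weights, edgeR 4.0.16 (quasi-likelihood with TMM) and DESeq2 1.42.0 (Wald test) on the recovered reads, a minimum of 2-fold, leaving out each library in turn, blocks by the replicate number in the title and by the numeral in the library name, the WT and KO tables for the interaction, and 1 fit over the reads of all 12 libraries. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, figures drawn with matplotlib 3.10.9, and tests run in R 4.3.3. Raw reads, transcript isoforms and exons were not analysed here, and no dose of DMXAA is given because the labels' value could not be checked.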

Results

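The 12 libraries ask how WT macrophages and macrophages labelled as knockouts of MGMT, a DNA repair protein that removes alkyl groups from guanine, answer the STING agonist DMXAA. Depth was 79.5 to 93.9 M reads for WT under DMSO, 85.1 to 92.5 for WT under DMXAA and 79.9 to 92.4 for KO under DMSO. Every library of KO under DMXAA, at 94.1 to 98.1, lay above all libraries of the other groups. The most abundant gene was Psap, which encodes the precursor of the lysosomal saposins, at 4.74 to 6.19% of the reads of a library. Lyz2, which encodes lysozyme, took 1.08% ± 0.038 (SD, n = 3) of the reads of WT under DMSO.

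Mgmt itself (chromosome 7, 136894614 to 137130266) was lower in KO but not absent. Its reads were 263, 245 and 243 in the WT libraries under DMSO and 121, 141 and 162 in the KO libraries, and 107, 85 and 99 against 51, 61 and 33 under DMXAA. The log2 difference of KO over WT was -0.83 (SE 0.166, adjusted p = 5.66e-03) under DMSO and -1.11 (SE 0.247, adjusted p = 9.05e-03) under DMXAA, with normalized counts of 250.2 ± 18.1 against 142 ± 31.4 and 99.9 ± 14.8 against 46.7 ± 13.3. The authors' deposited table gives -0.82 and -1.09 for the same differences. DMXAA lowered Mgmt in both genotypes, by log2 -1.04 (SE 0.153, adjusted p = 1.94e-04) in WT and -1.32 (SE 0.254, adjusted p = 9.71e-04) in KO, and these 2 responses differed by -0.28 (adjusted p = 6.73e-01 for the interaction). Reads are counted per gene, so a deletion of part of the gene that leaves other exons transcribed cannot be seen in them.

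Lyz2 (chromosome 10, 117277331 to 117282321) was also lower in KO, by log2 -0.66 (SE 0.056, adjusted p = 2.75e-05) under DMSO and -0.87 (SE 0.031, adjusted p = 1.46e-07) under DMXAA. Its neighbour Lyz1, a second lysozyme gene, was lower by -0.92 (adjusted p = 2.80e-02) and -1.01 (adjusted p = 6.89e-06). Xist, the X-inactivation transcript, differed by -0.10 and -0.08 and was not called in either comparison.

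**Figure D1:**
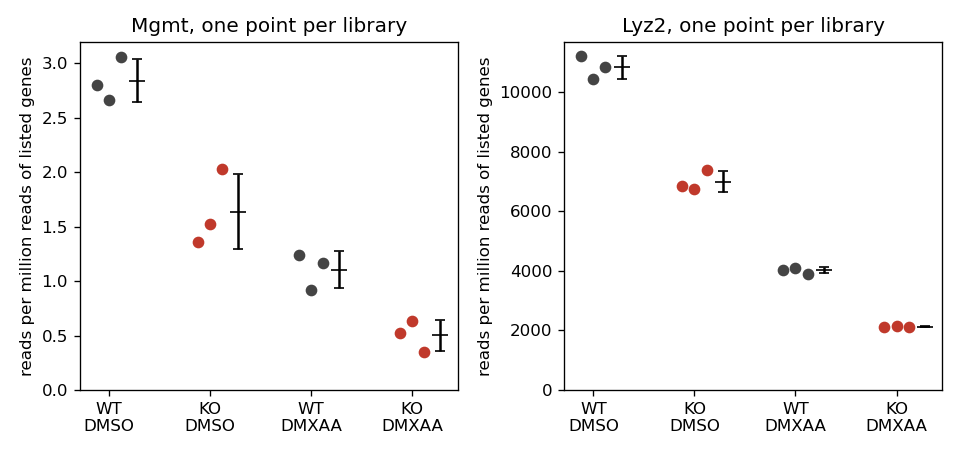
Reads of Mgmt and Lyz2 per M reads in listed genes, in each of the 12 libraries, with the mean and SD of each group (n = 3). Mgmt ranged from 2.67 to 3.06 in WT and 1.36 to 2.03 in KO under DMSO, and from 0.919 to 1.24 in WT and 0.351 to 0.636 in KO under DMXAA.

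In WT macrophages under DMXAA, all 44 tested interferon-stimulated genes rose, with a median log2 change of 3.46. The list had an adjusted p = 2.34e-24 at the preset correlation, 2.67e-01 with an estimated correlation and 1.47e-06 by fry. Among these genes was the ubiquitin-like protein gene Isg15 (chromosome 4, 156199424 to 156200818), which rose from 656 ± 66.7 to 34870 ± 918 normalized counts (log2 5.73, SE 0.072, adjusted p = 5.97e-12, n = 3 per group). All 18 interferon-inducible GTPases, which act against intracellular pathogens, rose as well (list adjusted p = 1.20e-12 at the preset correlation, 2.67e-01 with an estimated correlation). Gbp2 (chromosome 3, 142620602 to 142638008) rose from 420 ± 45.4 to 48600 ± 908 (log2 6.86, SE 0.074). The chemokine gene Ccl5 (chromosome 11, 83525778 to 83530518) rose from 1209 ± 378 to 221800 ± 17240 (log2 7.56, SE 0.168). Of 40 cell cycle genes 35 fell and 2 rose, and of 23 cholesterol synthesis genes 17 fell and 3 rose. Both lists were called at the preset correlation, but each had an adjusted p = 2.67e-01 with an estimated correlation. Hpgd, which encodes a prostaglandin-degrading enzyme, fell from 2572 ± 272 to 43.3 ± 7.88 (log2 -5.87, SE 0.145).

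In total 8007 of 12752 tested genes were called in WT, 4047 higher and 3960 lower, and 2403 of them changed at least 2-fold (1082 higher, 1321 lower). The groups did not overlap for 8771 genes (68.8%), where chance gives 10%. The authors' deposited table calls 7841 genes, 7636 of them called here in the same direction. The balance of directions rests on the scaling: 50.5% of called genes were higher as deposited, 37.4% with libraries rescaled to the same upper quartile and 22.4% with the same total, which move the median log2 change of all genes by -0.13 and -0.32.

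Among immune groups in WT, the interferon-stimulated genes (44 higher, 44 adjusted over the list alone) had a camera adjusted p = 2.34e-24 and an adjusted p = 2.67e-01 with an estimated correlation. Ifi44 (5.87) and the nucleic acid sensor Zbp1 (5.21) were among those with the smallest p. The GTPases (18 of 18 adjusted over the list alone, median 5.66) had an adjusted p = 1.20e-12 and an adjusted p = 2.67e-01 with an estimated correlation, with Tgtp2 at 6.78. MHC class I presentation rose in 20 of 20 genes (20 adjusted over the list alone, median 2.38; adjusted p = 5.32e-13, adjusted p = 2.67e-01 with an estimated correlation). H2-Q6 stood at 5.36, H2-Q7 at 4.82 and H2-T22 at 4.18. MHC class II rose in 9 of 10 and fell in 1 (10 adjusted over the list alone, median 1.05; adjusted p = 3.06e-03, adjusted p = 2.67e-01 with an estimated correlation). H2-Ab1 stood at 1.60 and Cd74 at 1.02. Of 20 chemokines 13 rose and 7 fell (20 adjusted over the list alone, median 1.24; adjusted p = 2.04e-02, adjusted p = 2.67e-01 with an estimated correlation). The monocyte attractant Ccl12 stood at 7.54 and the T cell attractant Cxcl10 at 6.82. Pattern recognition receptors rose in 15 and fell in 7 of 23 (22 adjusted over the list alone, median 0.78; adjusted p = 3.31e-02, adjusted p = 3.07e-01 with an estimated correlation). The RNA sensor Tlr3 rose by 2.65 and Cd14, a co-receptor for bacterial lipid, fell to -2.51. Cell death genes rose in 15 and fell in 5 of 26 (21 adjusted over the list alone, median 0.80; adjusted p = 1.20e-02, adjusted p = 2.67e-01 with an estimated correlation), and in 15 and 11 with libraries rescaled to the same total (median 0.48). The necroptosis effector Mlkl stood at 3.64 and the inflammatory caspase Casp4 at 2.68.

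Several immune groups held many called genes without passing the list test in WT, where 62.8% of all tested genes were called. The cGAS-STING pathway had 11 of 20 genes higher and 5 lower (16 adjusted over the list alone; adjusted p = 1.32e-01). The DNA exonuclease Trex1 stood at 2.81 and the nucleotide hydrolase Samhd1 at 2.26, and the list median turned from 0.18 to -0.14 with libraries rescaled to the same total. Cytokines had 9 of 17 higher and 4 lower (13 adjusted over the list alone, median 0.74; adjusted p = 8.86e-02). The death ligand Tnfsf10 stood at 6.07, the interleukin 1 antagonist Il1rn at 4.07 and Il15 at 2.78. NF-kappaB targets were split, 10 higher and 11 lower of 22 (21 adjusted over the list alone; adjusted p = 9.83e-01, median -0.04 but mean 0.19). Traf1 rose by 1.62 and Cd83 fell to -2.02. Classical activation markers were higher in 8 and lower in 4 of 15 (12 adjusted over the list alone, median 0.68; adjusted p = 9.61e-02). Acod1, which makes itaconate, stood at 4.74. Alternative activation markers were higher in 2 and lower in 7 of 14 (9 adjusted over the list alone, median -1.06; adjusted p = 8.86e-02). The haemoglobin scavenger receptor Cd163 stood at -4.97. Co-stimulatory and checkpoint ligands were higher in 9 and lower in 4 of 15 (13 adjusted over the list alone, median 0.61; adjusted p = 8.86e-02). Cd86 stood at 4.31 and Cd274, which encodes PD-L1, at 3.67.

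Among the other lists in WT, 4 described here were called down and 1 up. Cell cycle genes fell in 35 and rose in 2 of 40 (37 adjusted over the list alone, median -1.20; adjusted p = 1.39e-08, adjusted p = 2.67e-01 with an estimated correlation). The mitotic kinesin Kif20a stood at -1.61 and Prc1 at -1.59. The spindle gene Tpx2 ran the other way, at 3.04. Cholesterol synthesis fell in 17 and rose in 3 of 23 (20 adjusted over the list alone, median -0.73; adjusted p = 3.21e-04, adjusted p = 2.67e-01 with an estimated correlation). Sqle stood at -1.60. NRF2 targets, the antioxidant genes, fell in 13 and rose in 3 of 17 (17 adjusted over the list alone, median -0.86; adjusted p = 2.95e-03, adjusted p = 2.67e-01 with an estimated correlation). Gclm stood at -1.74 and Txnrd1 at -1.20. Ribosomal protein genes fell in 25 and rose in 3 of 30 (29 adjusted over the list alone, median -0.43; adjusted p = 8.49e-05, adjusted p = 5.05e-01 with an estimated correlation). Rpl3 stood at -1.31. Oxidative phosphorylation was higher in 18 and lower in 3 of 35 (21 adjusted over the list alone; adjusted p = 1.53e-02, adjusted p = 4.59e-01 with an estimated correlation). Cycs, the cytochrome c gene, rose by 1.53, but the list median of 0.17 became -0.15 with libraries rescaled to the same total. LXR targets and lipid handling had 11 of 18 lower and 4 higher (15 adjusted over the list alone, median -0.56; adjusted p = 6.06e-02), with Apoe, the lipid carrier, from 691300 ± 44420 to 209100 ± 3836 (log2 -1.72). Beside these lists, 6 of 8 monocyte markers were higher and 2 lower (median 3.20; adjusted p = 9.50e-02). Ly6c2 stood at 4.89 and Ccr2 at 1.52.

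In KO macrophages under DMXAA, all 44 interferon-stimulated genes and all 18 interferon-inducible GTPases rose, with medians of 4.19 and 6.11. At the preset correlation these lists had an adjusted p = 1.78e-24 and 8.61e-12, and with an estimated correlation 2.67e-01 and 2.38e-01. By fry each had an adjusted p = 6.67e-07. Slfn4 (chromosome 11, 83175186 to 83190216), a Schlafen family gene, rose from 78.9 ± 14.5 to 80710 ± 7263 normalized counts (log2 9.99, SE 0.121), Ccl5 from 300.3 ± 59.2 to 282700 ± 26290 (log2 9.89) and the GTPase Iigp1 from 25.4 ± 2.94 to 17110 ± 1225 (log2 9.35), n = 3 per group. The Wnt inhibitor Dkk2 fell from 218 ± 14.7 to 4.66 ± 2.60 (log2 -5.38, SE 0.36) and Igfbp4, which binds insulin-like growth factors, from 6887 ± 578 to 246 ± 24.8 (log2 -4.80, SE 0.091). The lipase gene Lipg had no reads in KO under DMSO and was at least 1310-fold higher under DMXAA.

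In KO 8462 of 12704 genes were called, 4282 higher and 4180 lower, 2559 of them at least 2-fold (1143 higher, 1416 lower), and the groups did not overlap for 9021 genes (71%, chance 10%). The authors' deposited table calls 8309, of which 8093 were called here in the same direction. The share of called genes that were higher was 50.6% as deposited, 36.8% with the same upper quartile and 20.3% with the same total, which move the median log2 change of all genes by -0.15 and -0.39.

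The interferon-stimulated genes in KO (44 adjusted over the list alone) had an adjusted p = 1.78e-24 and an adjusted p = 2.67e-01 with an estimated correlation, with Ms4a4c at 9.71, the tetherin gene Bst2 at 4.19 and Oas3 at 3.96. The GTPases (18 adjusted over the list alone) had an adjusted p = 8.61e-12 and an adjusted p = 2.38e-01 with an estimated correlation. MHC class I rose in 20 of 20 (20 adjusted over the list alone, median 2.42; adjusted p = 2.78e-12, adjusted p = 2.67e-01 with an estimated correlation). H2-Q7 stood at 5.02 and H2-Q4 at 3.45. MHC class II rose in 8 of 10 and 2 were not called (8 adjusted over the list alone, median 0.89; adjusted p = 1.06e-02, adjusted p = 4.63e-01 with an estimated correlation). Cd74 stood at 1.42. Chemokines rose in 13 and fell in 6 of 20 (19 adjusted over the list alone, median 1.40; adjusted p = 2.14e-02, adjusted p = 4.63e-01 with an estimated correlation). Ccl2 stood at 6.41. Pattern recognition receptors rose in 15 and fell in 6 of 23 (21 adjusted over the list alone, median 0.83; adjusted p = 2.20e-02, adjusted p = 4.29e-01 with an estimated correlation). Tlr9 stood at 2.12 and Tlr2 at -2.15. Cell death genes rose in 17 and fell in 8 of 26 (25 adjusted over the list alone, median 0.69; adjusted p = 3.04e-02, adjusted p = 4.63e-01 with an estimated correlation). Mlkl stood at 4.22.

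Outside immunity, cell cycle genes fell in 27 and rose in 4 of 40 in KO (31 adjusted over the list alone, median -0.69; adjusted p = 1.21e-03, adjusted p = 4.63e-01 with an estimated correlation). Prc1 stood at -1.74 and Tpx2 at 3.87. Cholesterol synthesis fell in 19 and rose in 2 of 23 (22 adjusted over the list alone, median -0.74; adjusted p = 2.79e-04, adjusted p = 2.38e-01 with an estimated correlation). The sterol carrier Stard4 stood at -2.28. Ribosomal protein genes fell in 26 and rose in 3 of 30 (29 adjusted over the list alone, median -0.57; adjusted p = 3.04e-06, adjusted p = 4.63e-01 with an estimated correlation). Rpl3 stood at -1.20. Oxidative phosphorylation was higher in 21 and lower in 3 of 35 (24 adjusted over the list alone; adjusted p = 3.23e-02, adjusted p = 6.14e-01 with an estimated correlation), but its median of 0.16 became -0.23 with libraries rescaled to the same total. Macrophage identity genes were higher in 6 and lower in 14 of 21 (20 adjusted over the list alone, median -0.48; adjusted p = 8.14e-02). The high-affinity Fc receptor Fcgr1 stood at 3.84 and Cd14 at -2.60. Beside these lists, markers of other cells in KO were not called as lists: monocyte markers were higher in 6 and lower in 2 of 8 (median 4.02; adjusted p = 8.54e-02), neutrophil markers higher in 3 of 4 (median 0.77; adjusted p = 1.96e-01) and stromal markers lower in 5 of 9 (median -1.85; adjusted p = 2.55e-01).

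The responses of the 2 genotypes were alike in direction. Across 12556 genes tested in both, the log2 changes had a Pearson correlation of 0.937 and a Spearman correlation of 0.904, with an orthogonal slope of KO on WT of 1.07; genes are not independent replicates, so no p is attached. Of these genes 3517 rose in both genotypes, where independent calls would give 1369, 3339 fell in both, where they would give 1292, and 48 were called in opposite directions.

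**Figure D2:**
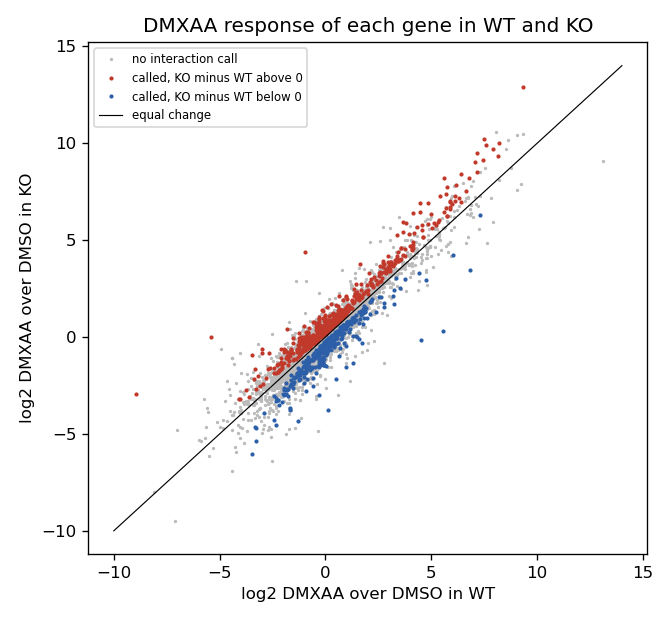
The log2 response to DMXAA of each gene in WT (horizontal) and KO (vertical), n = 3 libraries per group, with the line of equal change. Of the genes called for the interaction, 683 had a KO minus WT value above 0 and 412 below 0; with libraries rescaled to the same total the balance turned to 482 above and 748 below.

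Without DMXAA, most interferon-stimulated genes and all tested cell cycle genes were lower in KO than in WT. Both lists were called at the preset correlation, but not with an estimated correlation (adjusted p = 2.10e-01 for each). For interferon-stimulated genes the adjusted p was 3.01e-26 at the preset and 1.79e-03 by fry. Irf7 (chromosome 7, 141262706 to 141266481), a transcription factor of the interferon response, stood at 25720 ± 3451 normalized counts in WT and 6530 ± 926 in KO under DMSO (log2 -1.98, SE 0.108, adjusted p = 1.74e-06, n = 3 per group). Of 44 interferon-stimulated genes 40 were lower in KO, 0 higher and 4 not called, with a median of -0.74. All 40 tested cell cycle genes were lower, with a median of -1.11, among them Uhrf1, which maintains DNA methylation, at 5345 ± 749 against 1435 ± 216. The inducible heat shock gene Hspa1a (chromosome 17, 34969190 to 34972156) was at 979.5 ± 37.3 against 160.4 ± 19.9 (log2 -2.61, SE 0.112, adjusted p = 7.51e-07).

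Of 12814 genes tested under DMSO 2129 were called, 902 higher and 1227 lower in KO, and 373 differed at least 2-fold (67 higher, 306 lower). The groups did not overlap for 4451 genes (34.7%, chance 10%). The authors' deposited table calls 2344, of which 2042 were called here in the same direction. Among the named genes highest in KO were the lipid flippase Atp9a (chromosome 2, 168634438 to 168742409), Dkk2 (1.79) and Cd163, from 374 ± 46.6 to 952 ± 23.7 (1.35), and among the lowest Eps8l1, from 1402 ± 38.1 to 225 ± 41.0 (-2.65, SE 0.124), the helicase gene Pif1 (-2.35) and the fatty acid desaturase Fads2 (-2.33). Without replicate 1 of KO under DMSO 1399 genes were called, and with libraries rescaled to the same total the balance turned to 1126 higher and 1087 lower.

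Among immune lists under DMSO, 4 were called lower in KO and 1 higher, none of them with an estimated correlation. The interferon-stimulated genes (43 adjusted over the list alone) had an adjusted p = 3.01e-26 and an adjusted p = 2.10e-01 with an estimated correlation, with Oas1g at -1.10 and Oas3 at -0.77. Isg20, Ifih1, Parp9 and Dtx3l were the 4 not called. GTPases were lower in 10 of 16 and 6 were not called (14 adjusted over the list alone, median -0.61; adjusted p = 1.49e-06, adjusted p = 8.68e-02 with an estimated correlation). Tgtp2 (chromosome 11, 49057194 to 49064206) stood at 467 ± 38.9 against 147 ± 18.5 and Gbp6 at -1.27. MHC class I was lower in 10 of 20 and 10 were not called (11 adjusted over the list alone, median -0.17; adjusted p = 7.94e-05, adjusted p = 2.99e-01 with an estimated correlation). H2-Q6 stood at -0.95 and B2m, the light chain gene, at -0.45. Chemokines were lower in 8 of 17, 9 not called (10 adjusted over the list alone, median -0.24; adjusted p = 3.77e-02, adjusted p = 2.99e-01 with an estimated correlation). Ccl2 (chromosome 11, 82035571 to 82037453) stood at 284 ± 56.2 against 63.1 ± 10.5 and Ccl5 at -2.02. NF-kappaB targets went the other way, 8 higher and 3 lower of 22 (16 adjusted over the list alone, median 0.21; adjusted p = 1.33e-03, adjusted p = 2.10e-01 with an estimated correlation). Cd83 stood at 0.79, Nfkbiz at 0.50 and the prostaglandin synthase Ptgs2 at -2.23. In the cGAS-STING pathway 6 of 20 genes were lower and 2 higher (10 adjusted over the list alone; adjusted p = 6.63e-01, median 0.03 but mean -0.06). Sting1, which encodes the target of DMXAA, stood at -0.43 and the DNA sensor family member Ifi204 at -0.50. Markers of 2 other cell types moved with genotype beside these lists. Neutrophil markers were lower in KO in 4 of 7 (4 adjusted over the list alone, median -1.56; adjusted p = 1.41e-03, adjusted p = 2.99e-01 with an estimated correlation). S100a8 stood at 202 ± 42.7 against 66.8 ± 5.99. Stromal markers were higher in 5 of 8 (6 adjusted over the list alone, median 3.40, or 3.48 with Col6a1 at its bound; adjusted p = 1.27e-02, adjusted p = 2.99e-01 with an estimated correlation), where the collagen gene Col1a1 stood at normalized counts of 9.74, 184 and 219 in the KO libraries and 23.6, 0 and 0 in WT.

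Among the other lists under DMSO, the cell cycle (40 adjusted over the list alone) had an adjusted p = 9.35e-32 and an adjusted p = 2.10e-01 with an estimated correlation, with the replication helicase gene Mcm5 at -1.53 and Tpx2 at -1.20. Of all tested genes 16.6% were called under DMSO. Counts near that share, as for DNA repair and oxidative phosphorylation, say little about a list. DNA repair genes were lower in 7 of 39 and 32 were not called (7 adjusted over the list alone, median -0.05, adjusted p = 3.45e-02, adjusted p = 2.99e-01 with an estimated correlation). Brca1 stood at -1.46. LXR targets and lipid handling were lower in 12 of 18 (15 adjusted over the list alone, median -0.36; adjusted p = 1.89e-07, adjusted p = 8.68e-02 with an estimated correlation). The fatty acid receptor Cd36 stood at 145800 ± 7910 against 72120 ± 5223. NRF2 targets were lower in 8 of 17 (8 adjusted over the list alone, median -0.21; adjusted p = 8.83e-04, adjusted p = 2.99e-01 with an estimated correlation). The haem-degrading enzyme Hmox1 stood at 35930 ± 5658 against 16980 ± 689.7. Cholesterol synthesis was lower in 7 and higher in 1 of 23 (10 adjusted over the list alone, median -0.21; adjusted p = 5.42e-04, adjusted p = 3.74e-01 with an estimated correlation). Heat shock genes were lower in 3 of 10 (5 adjusted over the list alone, median -0.09; adjusted p = 1.43e-02, adjusted p = 5.04e-01 with an estimated correlation). Hspa1b stood at -2.42. Oxidative phosphorylation was lower in 6 of 35 (6 adjusted over the list alone, median -0.06, adjusted p = 4.14e-02, adjusted p = 6.93e-01 with an estimated correlation). With libraries rescaled to the same total 3 were lower (median -0.03). Ribosomal protein genes were higher in 12 of 30 (17 adjusted over the list alone, median 0.19; adjusted p = 1.81e-06, adjusted p = 5.21e-01 with an estimated correlation). Rpl23 stood at 0.33. Glycolysis and hypoxia genes were higher in 7 and lower in 2 of 27 (10 adjusted over the list alone, median 0.09; adjusted p = 3.77e-02, adjusted p = 5.21e-01 with an estimated correlation). Egln3 stood at 1.37. Macrophage identity genes were lower in 6 and higher in 1 of 21 (9 adjusted over the list alone, median -0.07; adjusted p = 6.86e-02), while Csf1r (0.08), Adgre1 (-0.03) and Cd68 (0.07) were not called.

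Under DMXAA the median genotype difference was -0.14 for interferon-stimulated genes (adjusted p = 4.71e-01 with an estimated correlation) and -0.73 for the cell cycle (adjusted p = 1.34e-02 with an estimated correlation). Both lists were called at the preset correlation. Under DMSO the medians of these lists were -0.74 and -1.11. The difference between treatments, tested as the interaction, was called for both at the preset correlation. With an estimated correlation it was not (adjusted p = 1.27e-01 and 4.85e-01). Isg15 stood at 32150 ± 882 normalized counts in WT and 23380 ± 526 in KO (log2 -0.46, SE 0.037, adjusted p = 1.69e-05, n = 3 per group). Cell cycle genes were lower in KO in 32 of 39 and higher in 1; the survivin gene Birc5 was at -2.13. Of 27 glycolysis and hypoxia genes 21 were higher in KO, 1 was lower and 5 were not called (list called at the preset correlation, adjusted p = 1.32e-01 with an estimated correlation). Pgk1, a glycolytic kinase gene, was at 12030 ± 451 against 20560 ± 471 (log2 0.77, SE 0.041). The fatty acid desaturase Scd2 (chromosome 19, 44293674 to 44306864) was at 268 ± 12.7 against 45.6 ± 4.41 (log2 -2.53), and the chemokine Cxcl9 at 5669 ± 472 against 12980 ± 190.1 (log2 1.20).

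Of 12499 genes tested under DMXAA 2686 were called, 1335 higher and 1351 lower in KO, 334 of them at least 2-fold (99 higher, 235 lower). The groups did not overlap for 4705 genes (37.6%, chance 10%). The authors' deposited table calls 2744, of which 2517 were called here in the same direction. With libraries rescaled to the same total 34.3% of called genes were higher in KO, against 49.7% as deposited. The named genes highest in KO included the phosphodiesterase Pde1c (2.07), Atp9a (1.99) and Cd34 (1.45), and the lowest the microtubule-associated Map2 (-2.99), the replication factor Pclaf (-2.30) and Eps8l1 (-2.24). Zfp618 had no reads in WT under DMXAA and was at least 74.6-fold higher in KO.

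Among immune lists under DMXAA, interferon-stimulated genes were lower in KO in 23, higher in 2 and not called in 19 of 44 (28 adjusted over the list alone; adjusted p = 8.09e-05, adjusted p = 4.71e-01 with an estimated correlation). The 2 higher were Irf7 (0.10) and Slfn5 (0.14) as deposited. With libraries rescaled to the same total or the same upper quartile 0 were higher. GTPases were lower in 13 and higher in 1 of 18 (14 adjusted over the list alone, median -0.26; adjusted p = 1.62e-05, adjusted p = 4.40e-01 with an estimated correlation). Gbp6 stood at -0.46. MHC class I was lower in 11 of 20 (15 adjusted over the list alone, median -0.13; adjusted p = 9.19e-05, adjusted p = 3.41e-01 with an estimated correlation). Tap2, a peptide transporter gene, stood at -0.35. MHC class II was lower in 6 of 10 (6 adjusted over the list alone, median -0.63; adjusted p = 6.08e-03, adjusted p = 1.61e-01 with an estimated correlation). H2-Aa stood at -0.74 and Cd74 at -0.76. Classical activation markers were lower in 10 of 15 (11 adjusted over the list alone, median -0.59; adjusted p = 3.84e-04, adjusted p = 2.42e-01 with an estimated correlation). The scavenger receptor Marco stood at -2.19 and the acute phase gene Saa3 at -1.06. Neutrophil markers again stood beside these lists, lower in 4 and higher in 1 of 7 (6 adjusted over the list alone, median -1.14; adjusted p = 2.40e-02, adjusted p = 2.10e-01 with an estimated correlation). S100a9 stood at 100.1 ± 9.24 against 3.88 ± 0.101. Cytokines (4 higher, 4 lower of 17), chemokines (6 higher, 5 lower of 17) and the cGAS-STING pathway (4 higher, 2 lower of 20) were not called.

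The cell cycle list under DMXAA (37 adjusted over the list alone) kept its call, adjusted p = 1.28e-19 at the preset and adjusted p = 1.34e-02 with an estimated correlation, with Prc1 at -1.31, Uhrf1 at -1.83 and Pcna, the sliding clamp gene, higher at 0.29. DNA repair was lower in 9 and higher in 1 of 39 (10 adjusted over the list alone, median -0.09; adjusted p = 2.92e-02, adjusted p = 1.78e-01 with an estimated correlation). Brca1 stood at -1.30. Targets of p53 were lower in 8 of 19 (8 adjusted over the list alone, median -0.20; adjusted p = 6.19e-04, adjusted p = 1.46e-01 with an estimated correlation). The cell cycle inhibitor Cdkn1a stood at -0.44. Glycolysis and hypoxia genes were higher in 21 and lower in 1 of 27 (23 adjusted over the list alone, median 0.35; adjusted p = 2.16e-10, adjusted p = 1.32e-01 with an estimated correlation). Gapdh stood at 0.60 and Tpi1 at 0.59. Genes of the integrated stress and unfolded protein responses were higher in 11 of 26 (12 adjusted over the list alone; adjusted p = 1.62e-02, adjusted p = 1.75e-01 with an estimated correlation), with Atf5 at 2796 ± 15.6 against 5750 ± 298, although the list median of 0.04 became -0.01 with libraries rescaled to the same total. NRF2 targets were higher in 6 and lower in 1 of 17 (10 adjusted over the list alone, median 0.15; adjusted p = 1.62e-02, adjusted p = 0.50 with an estimated correlation). Gsr stood at 0.41. Ribosomal protein genes were higher in 8 and lower in 1 of 30 (10 adjusted over the list alone, median 0.07; adjusted p = 1.23e-02, adjusted p = 0.50 with an estimated correlation), but in 1, with 1 lower, with libraries rescaled to the same total. Cholesterol synthesis was lower in 8 and higher in 1 of 23 (14 adjusted over the list alone, median -0.28; adjusted p = 4.16e-04, adjusted p = 1.32e-01 with an estimated correlation). LXR targets were lower in 8 of 17 (8 adjusted over the list alone, median -0.24; adjusted p = 1.14e-03, adjusted p = 1.32e-01 with an estimated correlation). The cholesterol exporter Abca1 stood at -0.62. Oxidative phosphorylation was lower in 8 of 35 (9 adjusted over the list alone, median -0.05, adjusted p = 1.03e-02, adjusted p = 2.96e-01 with an estimated correlation). That count is near the 21.5% called over all tested genes under DMXAA. Heat shock genes were lower in 6 and higher in 1 of 11 (8 adjusted over the list alone, median -0.20; adjusted p = 4.80e-04, adjusted p = 1.32e-01 with an estimated correlation). Hspa1a stood at -1.51.

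Genotype differences under the 2 treatments were related but far from identical: across 12263 genes the log2 differences had a Pearson correlation of 0.497 and a Spearman correlation of 0.373. Of these genes 344 were higher in KO under both treatments, where independent calls would give 94.8, 521 were lower in both, where they would give 129, and 103 were called in opposite directions.

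**Figure D3:**
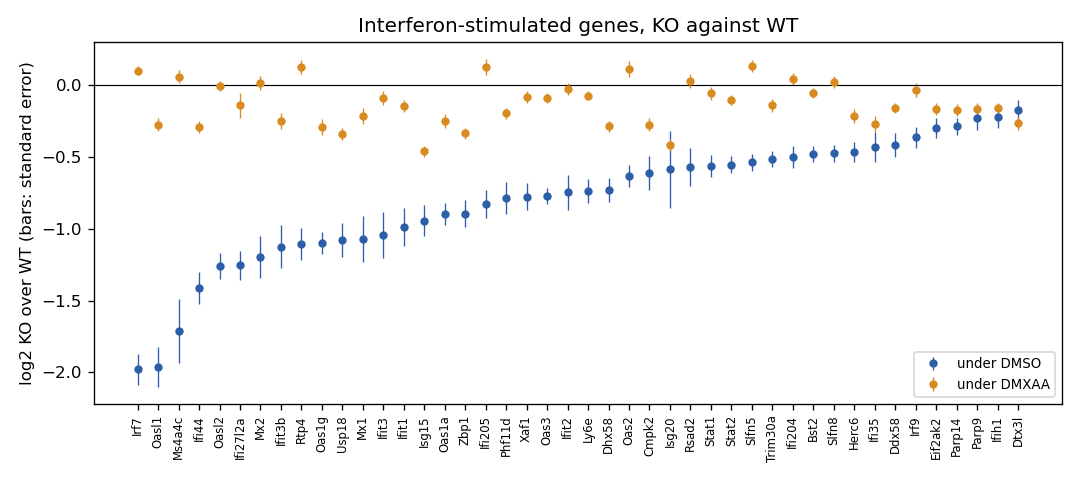
Log2 KO over WT with SE of each tested interferon-stimulated gene under DMSO and under DMXAA (n = 3 per group). The median was -0.74 under DMSO and -0.14 under DMXAA, lower in KO under both rescalings as well.

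The response to DMXAA itself differed between genotypes, and 34 of 44 interferon-stimulated genes rose further in KO. The list was called at the preset correlation, but not with an estimated correlation (adjusted p = 1.27e-01). The rise in KO mostly began from a lower level, as 40 of the 44 were lower in KO under DMSO. Under DMXAA 23 were lower in KO and 2 higher as deposited. Irf7 rose by 4.84 in WT and 6.93 in KO (difference 2.08), and the complement gene C3 (chromosome 17, 57203970 to 57228136) from 15050 ± 299 to 189300 ± 1106 in WT and from 5641 ± 499 to 238300 ± 5028 in KO (3.65 and 5.40, difference 1.75). Oas3 (0.69), Ifi209 (1.22) and Tgtp2 (1.44) differed in the same direction, n = 3 per group. Lacc1 (chromosome 14, 77024200 to 77036904), an immunometabolic enzyme gene, rose less in KO, by 0.68 against 1.77 (difference -1.09), and so did Tlr9, by 2.12 against 3.18 (-1.06).

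The interaction was called for 1095 of 12729 genes, 683 above 0 and 412 below, and 163 at a 2-fold difference (99 and 64). As deposited 62.4% of called genes were above 0, and 39.2% with libraries rescaled to the same total. Of the 683 genes above 0, 327 rose in both genotypes, 142 fell in both, 106 were called in KO alone, 72 in WT alone and 36 in opposite directions. Of the 412 below 0, 153 fell in both, 95 rose in both, 95 were called in KO alone, 56 in WT alone, 12 in opposite directions and 1 was not tested in both.

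By list, interferon-stimulated genes were above 0 in 34 and below in 0 of 44 (37 adjusted over the list alone, median 0.62; adjusted p = 1.21e-26, adjusted p = 1.27e-01 with an estimated correlation). GTPases were above 0 in 8 of 17 (10 adjusted over the list alone, median 0.48; adjusted p = 5.72e-05, adjusted p = 1.27e-01 with an estimated correlation). Chemokines were above 0 in 7 and below in 2 of 20 (11 adjusted over the list alone, median 0.40; adjusted p = 8.65e-03, adjusted p = 1.38e-01 with an estimated correlation). Ccl5 stood at 2.33 and Ccl2 at 2.26. NF-kappaB targets were below 0 in 10 of 22 and above in 0 (12 adjusted over the list alone, median -0.32; adjusted p = 7.73e-06, adjusted p = 1.38e-01 with an estimated correlation). The feedback inhibitor Tnfaip3 stood at -0.76 and Cd83 at -0.94. Classical activation markers were below 0 in 3 of 16 (4 adjusted over the list alone, median -0.36; adjusted p = 1.31e-02, adjusted p = 3.94e-01 with an estimated correlation). Marco stood at -1.87. Targets of p53 were below 0 in 5 and above in 1 of 19 (11 adjusted over the list alone, median -0.23; adjusted p = 8.99e-05, adjusted p = 8.87e-02 with an estimated correlation). Cell cycle genes were above 0 in 9 and below in 2 of 40 (18 adjusted over the list alone, median 0.24; adjusted p = 1.52e-04, adjusted p = 4.85e-01 with an estimated correlation). Pcna stood at 1.11 and the cyclin gene Ccnb2 at -2.17. NRF2 targets were above 0 in 8 of 17 (10 adjusted over the list alone, median 0.35; adjusted p = 3.37e-07, adjusted p = 1.38e-01 with an estimated correlation). Hmox1 stood at 1.28. Glycolysis and hypoxia genes were above 0 in 10 and below in 2 of 27 (15 adjusted over the list alone, median 0.33; adjusted p = 6.53e-06, adjusted p = 1.38e-01 with an estimated correlation). Pgk1 stood at 0.84. Lysosome and autophagy genes were above 0 in 9 and below in 1 of 28 (12 adjusted over the list alone; adjusted p = 4.54e-02, adjusted p = 6.37e-01 with an estimated correlation). The protease gene Ctsd stood at 0.45, but the list median of 0.07 was 0 with libraries rescaled to the same total. Ribosomal protein genes were below 0 in 2 of 30 (2 adjusted over the list alone, median -0.13, adjusted p = 4.66e-03, adjusted p = 6.88e-01 with an estimated correlation). That count does not exceed the 8.6% called over all tested genes for the interaction. In the cGAS-STING pathway, not called as a list, 5 of 20 genes were above 0 and 1 below. Samhd1 stood at 0.37 and Nlrc3, a negative regulator of STING signalling, at 1.09.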

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

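The tests of a smaller share of macrophages and of a driver allele at the Lyz2 locus were chosen only after the results were seen. So was that of a linked region around Mgmt. Rescaling, leaving out single libraries and other splits of the libraries were planned before. The patterns that rescaling and leaving out libraries were applied to here, and the bounds used, were taken from the observed values. The response to DMXAA differed between genotypes for 1095 genes, a difference between groups tested as an interaction. Of 100 drawn splits of genotype within treatment (of 200 possible) 1, the real one, gave as many genes and the highest other gave 575. Splits that mix the genotypes carry the genotype difference itself into their spread or their contrast. The split that swaps the genotypes in 1 treatment only was not among those drawn. These splits therefore cannot decide whether chance gave the interaction. For the 4 comparisons of 2 groups there are 10 splits of 6 libraries, too few for a share under 0.05: the real splits gave 8007 (WT response), 8462 (KO response), 2129 (genotype under DMSO) and 2686 (genotype under DMXAA), 1 split of 10 in each, and the highest other gave 0 in limma.

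A KO minus WT difference above 0 can be a larger rise or a smaller fall in KO. Named genes above 0 were C3 (difference 1.75), the membrane protein gene Ms4a6b (1.33), Ifi209 (1.22) and the protease Adam8 (0.87, from -0.27 in WT to 0.60 in KO). The others above 0 were Irf7 (2.08), Pcna (1.11), Oas3 (0.69), Tgtp2 (1.44), osteopontin, Spp1 (0.79), and Cd36 (0.95, a smaller fall, as DMXAA lowered it by log2 -1.08 in WT). Those with a smaller or more negative response in KO were Lacc1 (-1.09), Maged1 (-1.09, from -1.87 in WT to -2.96 in KO), Arl5c (-0.99), Arhgap19 (-0.89), Tlr2 (-0.94), heparanase, Hpse (-0.52), epoxide hydrolase, Ephx1 (-1.0), the phosphodiesterase Pde4b (-1.02), Plxnd1 (-0.78) and Tlr9 (-1.06). The 12 lists called for the interaction at the preset correlation, 0 of which camera called with an estimated correlation (adjusted p = 8.87e-02 to 6.88e-01) and 14 of all lists fry called, had median differences of 0.62 (interferon-stimulated genes), 0.48 (GTPases), 0.40 (chemokines), -0.32 (NF-kappaB targets), -0.36 (classical activation markers), 0.24 (cell cycle), -0.23 (p53 targets), 0.35 (NRF2 targets), 0.33 (glycolysis and hypoxia), 0.07 (lysosome and autophagy, 0 with equal totals), -0.13 (ribosomal proteins) and -0.25 (genes that differ between C57BL/6 substrains; adjusted p = 4.08e-02, adjusted p = 4.44e-01 with an estimated correlation, with 3 of its 5 genes called adjusted over the list alone and none over all genes in limma).

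Interferon-stimulated genes were lower in KO under DMSO, with a median log2 of -0.74 (bootstrap 95% interval over genes -0.90 to -0.56, list called at the preset correlation, adjusted p = 2.10e-01 with an estimated correlation). Neither scaling nor a single library accounts for this: the median was -0.71 in the less negative of the 2 rescalings, and between -0.81 and -0.66 with each library left out. A smaller share of macrophages in the KO cultures would lower macrophage genes in step, but the 20 tested macrophage identity genes other than Lyz2 had a median of -0.05 (-0.16 to 0.05). Neutrophil markers (median -1.56, 4 of 7 lower) and stromal markers (median 3.40, 5 of 8 higher) also differed by genotype under DMSO (adjusted p = 2.99e-01 with an estimated correlation for each), so a change in other cell types stays open, as do genotype itself and any difference between the mice or cultures, which coincide in this design; none of these was tested.

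Lyz2 was lower in KO under both treatments, and neither scaling (least negative log2 over both rescalings and treatments -0.63) nor a smaller share of macrophages (median of the other macrophage identity genes under DMXAA -0.02, bootstrap 95% interval -0.13 to 0.10) accounts for it. A candidate explanation is a Cre driver inserted at the Lyz2 locus, which would lower Lyz2 by about 1 copy. The difference was -0.87 under DMXAA and -0.66 under DMSO, each smaller than 1 log2 unit. That bound was set after the values were seen, so meeting it is no evidence for a driver. The labels name no driver but give WT as WTfl/fl. Lyz1 was the only 1 of 13 tested genes within 1 Mb that was called lower in both treatments. The expectation for these neighbours was set after the values were seen and excepted Lyz1, so it cannot speak for or against a driver. A driver allele and a regulatory change of Lyz2 cannot be told apart from gene counts.

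A set of 844 genes with a position differed between genotypes in the same direction under both treatments, which a chromosome segment around Mgmt carried over from another strain could give in part. Within 10 Mb of Mgmt 8.3% of tested genes (15 of 181) were in the set, against 7% elsewhere (Fisher exact p = 0.464, two-sided; upper exact 95% bound 13.3%). The share near Mgmt was thus not shown to exceed that elsewhere. With 181 tested genes there, the region could hold only a part of the 844 whatever its share. This comparison therefore cannot tell whether a segment accounts for some of the set. Differences elsewhere in the genome between the mice stay open, as untested.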

How the results depend on the processing

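Counts of called genes stayed within 1.5 times their reported value under the other pseudocounts, filters, scalings, variance models, tools and blocks, with these exceptions. Requiring 2-fold left 2403 genes (WT response), 2559 (KO response), 373 (genotype under DMSO), 334 (genotype under DMXAA) and 163 (interaction), fewer by construction. With each library left out, in groups then of 2 libraries, counts ran from 7350 to 7864, 7816 to 8138, 1399 to 1897, 2005 to 2270 and 831 to 1112 in the same order, and the correlation of the 2 responses from 0.931 to 0.935. The number of lists called by camera fell from 13, 11, 16, 17 and 12 to 0, 0, 0, 1 and 0 with an estimated correlation. In the same order fry called 34, 34, 21, 24 and 14. A higher correlation is not the cause for every list. GTPases in KO against WT under DMSO had an estimated correlation of -0.002, below the preset. Their unadjusted camera p still went from 1.70e-07 to 4.96e-03. For chemokines in the WT response (estimated correlation 0.002) it went from 6.06e-03 to 4.25e-02. The cause was not tested further. Of 12214 alternative values for 646 pairs of named gene and comparison, 11936 kept direction and side of the threshold, 195 lost the call, 81 gained it and 2 reversed with equal totals. The log2 of Blnk in the DMXAA response of WT went from 0.22 to -0.10 and the log2 of Blnk in the DMXAA response of KO from 0.30 to -0.085, the cause being the shift of all genes under that scaling. Replicate numbers in the titles did not pair samples (correlations of residuals -0.098 to 0.122). Depth limits calls among genes near the floor of 3 reads. With 3 libraries per group, 89.6% of 48 simulated 2-fold changes in the WT response were recovered, against 97.8% of 46 at 4-fold. That simulation changed a far smaller share of genes than the 62.8% called in the real WT response.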

Other observations

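No test in this part was chosen after its result was seen. Several further lists held genes called in both directions under DMXAA without passing the list test, where 62.8% of all tested genes were called in WT and 66.6% in KO. Dendritic cell markers were higher in 5 and lower in 2 of 7 in both genotypes (medians 2.39 in WT and 2.25 in KO; adjusted p = 3.19e-01 and 4.19e-01), with the chemokine receptor Xcr1 at 5.91 and 7.18 and the integrin Itgax at -1.10 in WT. Macrophage identity genes in WT were higher in 6 and lower in 11 of 21 (17 adjusted over the list alone, median -0.22; adjusted p = 1.19e-01). Fcgr1 stood at 3.31, the efferocytosis receptor Axl at 1.81 and Cd14 at -2.51. Immediate early genes were higher in 5 and lower in 7 of 14 in WT (median -0.33; adjusted p = 5.42e-01). The nuclear receptor Nr4a1 stood at -3.62 and Klf6 at 1.05, and in KO Nr4a1 was at -3.49 and the phosphatase Dusp1 at 1.45. Osteoclast genes were higher in 2 and lower in 3 of 8 in WT (median -0.40; adjusted p = 5.42e-01). The protease Ctsk stood at 1.76 and the fusion protein Dcstamp at -3.01. Under DMSO Dcstamp was lower in KO (-1.73), as was the tartrate-resistant phosphatase Acp5 (-0.80), among 3 lower and 1 higher of 8 osteoclast genes (adjusted p = 7.06e-01).

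Other lists that did not pass the list test also held called genes. Of all tested genes 62.8% were called in the WT response and 66.6% in the KO response. Counts near these shares say little about a list. The integrated stress and unfolded protein responses were higher in 13 and lower in 7 of 26 in WT (adjusted p = 1.52e-01; median 0.22, but -0.10 with equal totals) and higher in 15 and lower in 7 in KO (adjusted p = 1.26e-01; median 0.25, but -0.14 with equal totals). The stress transcription factor Ddit3 stood at 2.28 and 3.12 and Atf4 at 1.55 and 1.82. Under DMSO the pseudokinase Trib3, a target of that response, was at 76.4 ± 13.5 normalized counts in WT and 268 ± 18.9 in KO (log2 1.81, SE 0.164, n = 3 per group). p53 targets were higher in 8 and lower in 4 of 20 in WT (adjusted p = 4.57e-01; median 0.11, but -0.21 with equal totals). Mdm2 stood at 0.81 and Sesn1 at -2.27. DNA repair genes were higher in 6 and lower in 19 of 39 in WT (26 adjusted over the list alone, median -0.28; adjusted p = 1.62e-01). Lig1 stood at -0.85, and higher in 10 and lower in 18 in KO, with Parp1 at -0.74. Glycolysis and hypoxia genes were higher in 6 and lower in 15 of 27 in WT (median -0.17; adjusted p = 1.57e-01) and higher in 13 and lower in 8 in KO (adjusted p = 4.45e-01; median 0.14 but mean -0.08, and median -0.25 with equal totals). The regulator Pfkfb3 stood at 1.56 and 1.51. Lysosome and autophagy genes were split in WT, 10 higher and 10 lower of 28 (adjusted p = 8.42e-01; median 0.01, but -0.31 with equal totals). The sterol carrier Npc2 stood at 1.41 and the proton pump subunit Atp6v0d2 at -1.97. Heat shock genes were also split, 4 higher and 4 lower of 11 (adjusted p = 9.64e-01; median 0.03, but -0.29 with equal totals). Hspa8 stood at 0.45.

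Markers of other cells were few. In WT under DMXAA neutrophil markers were higher in 1 and lower in 3 of 7 (median -0.43; adjusted p = 5.42e-01), B cell markers higher in 2 and lower in 1 of 3, T and NK cell markers higher in 2 of 2, stromal markers higher in 1 of 3, mast cell and basophil markers higher in 1 and lower in 1 of 3 (median -1.19 but mean 0.87), endothelial and megakaryocyte markers higher in 2 and lower in 1 of 5 (median 0.17, but -0.12 with equal totals), and sex-linked genes higher in 1 of 2. In the KO response neutrophil markers were higher in 3 and lower in 0 of 4 (median 0.77; adjusted p = 1.96e-01). No mitochondrially encoded transcript or erythroid marker was listed with enough counts to be tested, and Y-linked genes were not tested.

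Genes near Mgmt were lower in 11 and higher in 2 of 18 in the WT response (14 adjusted over the list alone, median -0.42; adjusted p = 3.31e-02, adjusted p = 2.67e-01 with an estimated correlation). Dock1 stood at -1.48. In the KO response 12 were lower and 2 higher of 18, and the list was not called (median -0.25; adjusted p = 8.14e-02). Between genotypes 2 were higher and 2 lower under DMSO (adjusted p = 5.18e-01) and 5 higher and 1 lower under DMXAA (adjusted p = 9.97e-02). Genes that differ between C57BL/6 substrains were higher in 1 of 5 in KO under DMSO (median 0.04; adjusted p = 5.12e-01) and higher in 1 and lower in 3 of 5 under DMXAA (median -0.25; adjusted p = 3.17e-01). The mitochondrial transhydrogenase gene Nnt differed between genotypes by 0.04 under DMSO, not called. The log2 of Nnt in KO against WT under DMXAA was -0.245 (adjusted p = 2.44e-02). That call was lost without WT replicate 1 (-0.20) or 3 (-0.25) and without KO replicate 2 (-0.25) or 3 (-0.21). Wdfy1, an adaptor of Toll-like receptor signalling in the substrain list, rose by 1.60 in WT and 1.63 in KO.

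Beyond the genes given so far, Klrk1 had no reads in WT under DMSO and was at least 679-fold higher under DMXAA, and Zfp618 had none in WT under DMXAA, at least 456-fold lower than under DMSO. Cxcl9 in KO rose from 3 reads over the DMSO group, a ratio of 15900 (95% counting interval 5440 to 77000).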
